A study of Mus musculus with 4 samples.

How the data were processed

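Gene expression was measured on 4 Affymetrix whole-transcript arrays, 1 per sample, from lineage-negative, c-Kit-positive cells (LK cells, a fraction rich in hematopoietic stem and progenitor cells) of NOD mice, the non-obese diabetic strain. Per the labels, 2 samples were held for 4 h at 37 °C with vehicle (DMSO) and 2 with dimethyl prostaglandin E2 (dmPGE2, 10 µM) together with dexamethasone (10 µM). Total RNA was purified with a PicoPure kit and 10 ng was amplified and biotin-labelled with the GeneChip WT Pico kit, per the labels' protocols. The series' design text calls the duplicates biological, and the source of the cells in each duplicate is not given in the sources used here.

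The deposited values are log2 signals that the authors made with RMA in the Transcriptome Analysis Console, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. The versions of both and the genome build are not given in the sources used here. RMA forces the arrays towards 1 distribution, so a change of total RNA per cell cannot be seen, and low signals are compressed towards the background, so folds of dim genes are understated. Array medians lay between 4.36 and 4.44. The 23 background probe sets averaged 3.07 to 3.16 per array, and single ones reached 5.55. Arrays carry no read depth, and their number, 2 per group, limits the precision.

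The value table held 72688 rows. Left out were 31 AFFX rows, 5222 negative and 1324 positive control rows and 155 ERCC rows, 6732 in all, which left 65956 features. The plan made before the data were examined named only AFFX rows and rows that a table marks as controls. The other control rows were recognised by their identifiers afterwards, so leaving them out departs from the plan. The fit with all control rows kept was added as an alternative, and 0 features passed limma's threshold there. Of the features, 30604 had exactly 1 gene symbol in the platform annotation, 2146 had several and stayed unnamed, and 33206 had no gene listed there. Entrez identifiers matched the RefSeq gene table of assembly GRCm38.p6 for 22818 features, which updated 827 symbols. The result was 30142 genes, 19046 of them protein-coding. For the 355 genes with more than 1 feature, the feature with the highest mean over the 4 arrays was used. No coordinates are given.

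The test was limma's moderated test (lmFit and eBayes, limma 3.58.1 in R 4.3.3), two-sided, on the log2 values of all 65956 features with group as the only term. P-values were adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. The residual degrees of freedom were 2, and limma's prior added 2.59 with a prior SD of 0.165. Standard errors (SE) are limma's moderated ones, and SDs are over the 2 arrays of a group. Fixed before the data were examined were the fit, the alternatives, 27 gene lists (18 of pathways and functions, 9 of cell type markers) and the rule for named genes. Each list was tested with camera on 1 feature per gene, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. Beside it stood camera with the correlation estimated per list and fry. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, which leaves it little power. A large adjusted p there thus does not show that correlation between members undid a call. Members were also tested with limma's p adjusted over the list alone. A list's median was set against 10000 random lists matched on signal in bins of 300 genes and drawn gene by gene.

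The naming rule had 3 parts. The first was 14 genes named in any case, of which Areg is not analysed here. The second was the 12 largest rises and falls among genes past the threshold whose combination arrays both lay beyond both vehicle arrays, and it left 1 gene. The third was, per list, up to 4 members past the threshold, or the 2 with the smallest p where fewer than 2 passed. Members past the threshold over the list alone, and the 12 largest differences in each direction under the console's default threshold (unadjusted p under 0.05 and a 2-fold difference), were named beyond this rule, after their values were seen. Predicted genes, small RNAs and receptor segments were not named.

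On simulated data, drawn for the 65956 features of this comparison from their means and limma's prior in 20 simulations of 200 changed features, the fit called 0% of those changed by 1 on the log2 scale, 43.1% by 2, 81.4% by 3 and 94.1% by 5. On average, 5.2 unchanged features per simulation were called. Camera found a list of 28 members shifted by -0.35 in 20 of 20 simulations and called an unshifted list in 1. The simulated noise was independent between features and held no difference between the replicate numbers. The shares called need not hold for the real arrays, which have such a difference.

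The alternatives were the replicate number as a block, an intensity trend or a robust prior in eBayes, 2 filters on dim features, features with 1 symbol only, 2 rescalings of the arrays, each array left out in turn, 3 other thresholds, the mean of a gene's features, and camera with an estimated correlation. Added after seeing the data were keeping the control rows, leaving out 1187 features whose values repeat another feature's exactly, and protein-coding genes only in the list tests. Figures were drawn with matplotlib 3.10.9.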

Results

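The 4 arrays compared LK cells of NOD mice after 4 h in culture with vehicle or with dmPGE2 plus dexamethasone. The first drug is a long-lived analog of prostaglandin E2, which signals through cAMP, and the second is a synthetic glucocorticoid. There were 2 samples per group, numbered 1 and 2 in each. The series title links the cells to experimental autoimmune diabetes, and the comparison asks which transcripts differ once the cells have met both drugs. No array carried either drug alone, so their separate shares cannot be read. Values are RMA signals on the log2 scale, given as mean ± SD (n = 2), and differences are combination minus vehicle.

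Tlr8, an endosomal sensor of single-stranded RNA, rose from 5.37 ± 0.13 to 9.96 ± 0.03 after the combination. This is 24.0-fold, a log2 difference of 4.58 (SE 0.14) with an adjusted p of 0.041 in limma. In this main fit it was the only named gene past the threshold over all 65956 features. The other feature that passed, TC0700002949.mm.1, has no gene listed in the annotation and rose from 7.00 ± 0.07 to 11.74 ± 0.09. With all control rows kept, which is closer to the plan, 0 features passed and limma's adjusted p for Tlr8 was 0.18. With the replicate number as a block, 11 genes passed, Tlr8 among them. Beyond Tlr8 and the unnamed feature, further genes had large differences that missed the threshold over all features in the main fit. Il1r2, the decoy receptor for interleukin-1, was at 4.61 ± 0.35 with vehicle and 10.60 ± 0.49 with the combination, a 63.7-fold difference (SE 0.31, limma adjusted p = 0.094). Ppbp, a platelet chemokine, differed by 5.52, the lectin Clec4d by 5.48, thrombospondin 1 (Thbs1) by 4.91 and Trem1, an amplifier of myeloid inflammation, by 4.75. Pdcd1, which encodes the inhibitory receptor PD-1, was at 5.13 ± 0.41 against 9.63 ± 0.43, and the metalloprotease Adam8 at 8.16 ± 0.63 against 12.54 ± 0.77. With Havcr2, Cxcl2, Ccr1 and Cxcr2, given with their lists, these are the 12 largest upward differences, and they were picked after their values were seen. The vehicle means of Il1r2, Ppbp, Cxcl2, Ccr1, Tlr8, Pdcd1 and Havcr2 lay within the range of single background probe sets, up to 5.55. The same holds for the vehicle means of Ptgs2, Fos, Pde4b, Errfi1, Mertk, Pik3ip1, Sgk1, Socs1, Traf1, C1qb and Btg1 and the combination means of Tnf, Ciita, Ptger4 and Gbp2. Both means lay there for Abca1, Nr4a1, Nr4a3, Ptger2, Blnk, Ebf1, Clec1b and Cd8a. All of these are given with their lists, and the folds of the genes named here may be understated.

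In the other direction no gene passed the threshold over all features in the main limma fit. Lpl alone passed with the replicate number as a block (limma adjusted p = 0.047). At an unadjusted p under 0.05 in limma, 798 of the 30142 genes were lower and 802 higher. Of all features 5.58% passed it, near the share of 0.05 that would pass with no difference. Lipoprotein lipase (Lpl) was at 8.36 ± 0.05 with vehicle and 4.81 ± 0.27 with the combination, 11.7-fold lower (limma adjusted p = 0.094). Il2ra, the alpha chain of the interleukin-2 receptor, was at 8.96 ± 0.17 against 6.26 ± 0.25. The transcription factor Irf4 was at 7.16 ± 0.01 against 5.05 ± 0.06, and Il6st, the gp130 subunit of interleukin-6 family receptors, at 11.67 ± 0.47 against 9.58 ± 0.76. Elovl7, which elongates fatty acids, differed by -3.21, Rassf4 by -2.82, Gria3 by -2.41, Mc5r by -2.31 and Stap1 by -2.15. Clec7a, the beta-glucan receptor Dectin-1, had the largest downward difference, -3.69, but its combination arrays lay far apart (8.08 ± 2.79). The combination means of Lpl, Irf4 and Mc5r (4.45) lay within the range of single background probe sets, so their differences may be understated. These genes too were picked after their values were seen.

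**Figure D1:**
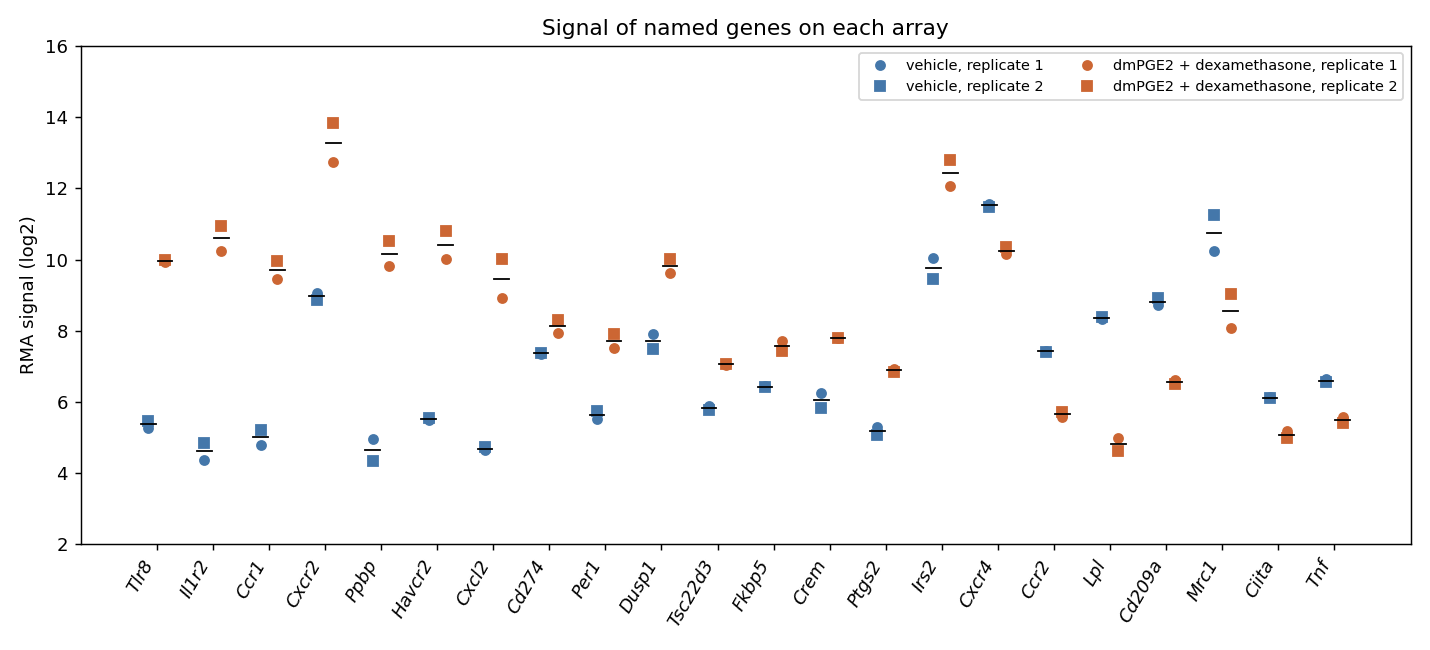
RMA signal (log2, vertical axis) of 22 named genes on the 4 arrays, with vehicle in blue, the combination in orange, circles for replicate 1, squares for replicate 2 and a black line at each group mean. Both combination arrays lie above both vehicle arrays for genes such as Tlr8 (5.37 against 9.96) and below them for genes such as Lpl (8.36 against 4.81).

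At gene level the counts depended on the threshold and on the fit, which with the replicate number as a block passed 19 features and 11 genes. With limma and Benjamini-Hochberg adjustment, 2 features passed 0.05, and 11 passed 0.10, with the genes Tlr8, Il18rap, F13a1, Il1r2, Ccr1 and, lower in the combination, Lpl. The console's default threshold took 217 genes higher and 103 lower, without correction for multiple tests. Leaving out any 1 array ended the call of Tlr8. Such a fit leaves 1 array in a group and fewer residual degrees of freedom. The lost call alone thus does not show that the difference rests on 1 array. The log2 difference of Tlr8 stayed between 4.49 and 4.68 in these fits. On all 4 arrays the call also ended with an intensity trend (adjusted p = 0.083), with filters on dim features at the median and the 25th percentile (0.051 and 0.052), after a second quantile normalization (0.067) and with the control rows kept (0.18).

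Targets of the glucocorticoid receptor were the list with the most calls. Of 30 measured members, 15 rose and 0 fell with p adjusted over the list alone in limma, and 0 passed over all features. Besides Il1r2 they included the clock gene Per1, which rose 4.20-fold to 7.71 ± 0.27, the phosphatase gene Dusp1, 4.29-fold to 9.81 ± 0.28, and Nfkbia, which encodes an inhibitor of NF-kB, 3.75-fold to 10.34 ± 0.28. The glucocorticoid-induced leucine zipper gene Tsc22d3 rose 2.33-fold to 7.06 ± 0.02, and Fkbp5, a cochaperone of the receptor, rose 2.20-fold to 7.57 ± 0.22. The other members that rose were Txnip, Ddit4, Tgm2, Klf9, Sgk1, Pik3ip1, Errfi1, Zbtb16 and Mertk, by 0.52 to 1.76 on the log2 scale. The list's median difference was 0.73, with 0.77 between the arrays numbered 1 and 0.66 between those numbered 2, and its median lay above those of all 10000 random lists of matched signal. Camera placed the list above other genes (adjusted p = 1.6e-14 with the preset correlation, and adjusted p = 0.31 with an estimated correlation). Fry, which asks whether members move one way on balance, gave an adjusted p of 0.038, its only call among the 27 lists. With the replicate number as a block, fry's adjusted p for this list was 0.15. The block leaves fewer residual degrees of freedom than the 2 of the main fit. The larger p thus does not show that the block undid the call. Of the 15 calls, 4 were lost without at least 1 array: Ddit4, whose log2 difference then stayed between 1.10 and 1.79, Errfi1 (0.47 to 1.01), Mertk (0.46 to 0.58) and Zbtb16 (0.65 to 0.81).

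Genes that respond to cAMP through CREB were the list with the second highest median. In limma 7 of 27 measured members rose over the list alone and 0 fell. Irs2, an adaptor of insulin signalling, rose 6.39-fold from 9.76 ± 0.41 to 12.43 ± 0.53. Crem, a cAMP-induced transcription factor, rose 3.37-fold from 6.04 ± 0.31 to 7.79 ± 0.01, Ptgs2 (cyclooxygenase-2) 3.25-fold, Fos 2.82-fold and the phosphodiesterase gene Pde4b 2.26-fold. The other 2 were Per1 and Dusp1, which both lists hold. The orphan receptor genes Nr4a1, Nr4a2 and Nr4a3 did not pass and differed by 0.50, -0.05 and 0.43. Nr4a1 and Nr4a3 lay within the range of single background probe sets in both groups. The median was 0.32, with 0.25 for number 1 and 0.50 for number 2, and 0.19 without combination 2. Fos and Pde4b lost their calls without vehicle 1 and without vehicle 2, with log2 differences of 1.40 and 1.12 and of 1.60 and 1.24, and without combination 2 they differed by 0.98 and 0.78, where Pde4b did not pass. Camera's adjusted p was 3.7e-09 with the preset correlation, and the adjusted p was 0.75 with an estimated correlation.

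Among 27 measured components of prostaglandin and glucocorticoid signalling, Ptgs2 and Fkbp5 rose over the list alone and 0 fell, against 3 and 2 with the replicate number as a block. The count was 1 without vehicle 1, 1 without vehicle 2 and 3 without combination 1, and the log2 difference stayed between 1.58 and 1.82 for Ptgs2 and between 0.99 and 1.29 for Fkbp5. The prostaglandin E2 receptor gene Ptger4 was at 5.81 ± 0.33 with vehicle and 4.78 ± 0.20 with the combination, and Ptger2 at 5.10 ± 0.08 and 5.29 ± 0.19. The glucocorticoid receptor gene Nr3c1 was at 8.31 ± 0.09 and 8.15 ± 0.49. None of these 3 passed limma's test. The list's median was -0.08 and its mean 0.04, with camera pointing down (adjusted p = 0.95).

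Of 30 measured immune regulatory molecules, 5 rose over the list alone and 0 fell in limma. Havcr2, the inhibitory receptor TIM-3, rose 29.9-fold from 5.51 ± 0.05 to 10.42 ± 0.55. Ptgs2 rose as given, Fgl2, a secreted immunosuppressive fibrinogen-like protein gene, 2.16-fold, and the cytokine signalling inhibitor Socs1 1.65-fold. Cd274, which encodes PD-L1, rose 1.69-fold from 7.36 ± 0.01 to 8.13 ± 0.25, close to the limit (limma p adjusted over the list alone = 0.0496). Ido1, which degrades tryptophan, stayed near background at 3.91 ± 0.26 and 3.99 ± 0.15. The list's median was 0.20 (0.19 and 0.22 for numbers 1 and 2), with camera's adjusted p at 1.0e-05 and an adjusted p of 0.71 with an estimated correlation. The count of 5 was 3 without vehicle 1, 2 without vehicle 2 and 2 without combination 2, while the log2 difference of Fgl2 stayed between 0.92 and 1.31, that of Socs1 between 0.63 and 0.81 and that of Cd274 between 0.58 and 0.94.

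Homing and adhesion molecules moved in both directions. In limma, 3 of 28 measured members rose and 2 fell over the list alone. The chemokine receptor genes Ccr1 and Cxcr2 rose by 4.70 to 9.70 ± 0.35 and by 4.32 to 13.29 ± 0.76 on the log2 scale, and the integrin gene Itgam by 1.25, a call lost without vehicle 1 (1.43), vehicle 2 (1.07) and combination 2 (0.95). Ccr2, a receptor of monocyte chemokines, fell 3.41-fold from 7.42 ± 0.02 to 5.65 ± 0.10. Cxcr4, the receptor that retains stem cells in the marrow, fell 2.42-fold from 11.52 ± 0.06 to 10.25 ± 0.14. The median was -0.10 and the mean 0.20. Camera pointed down and did not call the list (adjusted p = 0.45). Fry's test of change in either direction, which passed for 13 of the 27 lists, gave an adjusted p of 0.0024. With the replicate number as a block, this test of fry gave an adjusted p of 0.060. The block costs a residual degree of freedom here too, so the larger p does not show that the block undid the call.

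Of 29 measured NF-kB and inflammatory cytokine genes, 4 rose and 1 fell over the list alone in limma. The neutrophil chemokine genes Cxcl2 and Cxcl3 rose 27.5-fold, to 9.47 ± 0.78, and 6.81-fold, to 8.39 ± 0.50, and Nfkbia and Traf1 rose 3.75-fold and 1.66-fold. Nfkbia, an inhibitor of the pathway, is also in the glucocorticoid list. Tnf fell 2.16-fold from 6.60 ± 0.07 to 5.49 ± 0.12. The 5 calls became 3 without vehicle 1 and 8 without combination 1, with the log2 difference of Traf1 between 0.66 and 0.79 and that of Tnf between -1.19 and -1.03. Camera called the list upward (adjusted p = 0.035, and adjusted p = 0.75 with an estimated correlation), with a mean of 0.46. Its median was 0.01 and turned to -0.02 after a second quantile normalization and to -0.04 after centring the arrays, and it lay between 0.08 and 0.10 without 1 array. Without vehicle 1 or combination 2, camera's adjusted p was 0.11 or 0.082.

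Among 22 measured antigen presentation genes, 1 rose and 2 fell over the list alone in limma. Cd80, a costimulatory ligand, rose 11.6-fold from 5.80 ± 0.01 to 9.34 ± 1.25. Ciita, the master regulator of MHC class II, fell 2.05-fold from 6.11 ± 0.02 to 5.08 ± 0.14, and its target H2-Ab1 fell 1.92-fold from 8.20 ± 0.04 to 7.26 ± 0.10. The median was -0.18, and camera's adjusted p was 0.031 (adjusted p = 0.75 with an estimated correlation). The 3 calls became 0 without vehicle 1, 0 without vehicle 2 and 1 without combination 2, while the log2 difference stayed between -1.13 and -0.94 for Ciita, -1.01 and -0.87 for H2-Ab1 and 2.65 and 4.41 for Cd80. Camera's adjusted p was 0.40 without vehicle 1 and 0.29 without combination 2, with medians of 0.01 and -0.01, against -0.30 without vehicle 2 and -0.32 without combination 1.

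**Figure D2:**
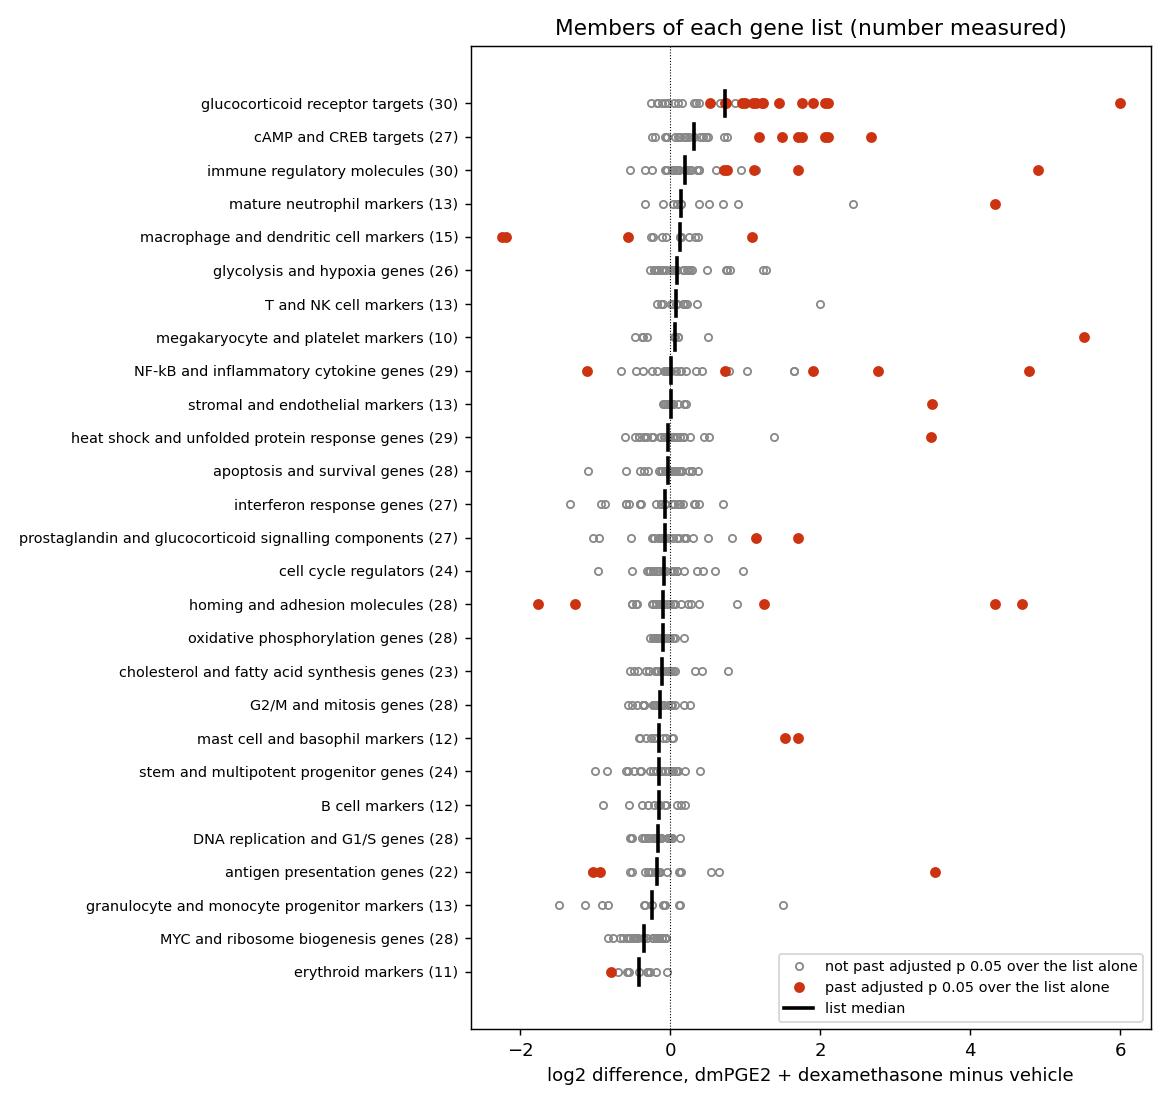
Log2 difference, combination minus vehicle (horizontal axis), of each measured member of the 27 gene lists (rows, with the number measured), where filled red points pass limma's p adjusted over the list alone, open grey points do not, and black bars are list medians. Glucocorticoid receptor targets have the highest median, 0.73, and erythroid markers the lowest, -0.42.

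Camera called 5 further pathway lists downward, in which no member passed alone. All 28 measured MYC and ribosome biogenesis genes were lower, with a median of -0.36 (-0.34 for number 1 and -0.33 for number 2, and -0.23 without vehicle 1). Polr1b, a subunit of RNA polymerase I, was at 9.36 ± 0.10 and 8.54 ± 0.08, and Max, the partner of MYC, at 13.31 ± 0.17 and 12.64 ± 0.06. Camera called this list downward (adjusted p = 2.9e-12, and adjusted p = 0.75 with an estimated correlation), and 11 members had an unadjusted p under 0.05. The medians were -0.16 for DNA replication and G1/S genes, -0.14 for G2/M and mitosis genes, -0.10 for oxidative phosphorylation genes and -0.15 for stem and multipotent progenitor genes. Camera's adjusted p for these was 0.0032, 0.0032, 0.0077 and 0.015, and with an estimated correlation the adjusted p was 0.75 for each. E2f1 and Rfc3 differed by -0.52 and -0.33, Bub1 and Bub1b by -0.37 and -0.35, Ndufb8 and Uqcrc1 by -0.22 and -0.28, and the stem cell genes Lmo2 and Erg by -0.59 and -0.57. The arrays numbered 1 carried most of the replication and mitosis shifts, with medians of -0.26 and -0.32 against -0.06 and -0.03 for number 2. Camera lost both, and oxidative phosphorylation, without vehicle 1 (adjusted p = 0.84, 0.96 and 0.44) and without combination 2 (0.12, 0.060 and 0.060). The medians were then -0.0020, 0.01 and -0.06 without vehicle 1 and -0.10, -0.13 and -0.07 without combination 2, against -0.42, -0.30 and -0.16 without vehicle 2 and -0.32, -0.17 and -0.11 without combination 1. It lost the stem cell list without vehicle 2 (0.18, with the median at -0.03) and without combination 1 (0.21, at -0.06). Replication and mitosis genes also differed between the numbers, by -0.44 and -0.38 on the vehicle arrays and by -0.21 and -0.04 on the combination arrays.

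Camera called none of 5 further pathway lists. Slc7a11, the cystine transporter, rose 11.2-fold over the list alone among 29 heat shock and unfolded protein response genes, a call lost without vehicle 1 and without vehicle 2, where its log2 difference was 3.72 and 3.24 against 3.48 on all arrays, while the serine synthesis gene Phgdh differed by -0.61. This list's median was -0.03 and its mean 0.10, with camera pointing down (adjusted p = 0.45). In the 26 glycolysis and hypoxia genes (median 0.08, camera adjusted p = 0.12) no member passed, while 5 rose with the replicate number as a block. Hif1a was at 11.04 ± 0.17 and 12.32 ± 0.48 and Pfkfb4 at 6.46 ± 0.03 and 7.20 ± 0.13. Leaving out combination 1 gave 1 call there. Apoptosis and survival genes had a median of -0.03 (camera adjusted p = 0.58), with Pim2 at -1.10 and Tnfrsf10b at -0.40, and 1 member passed without vehicle 1. Cell cycle regulators had a median of -0.08 (adjusted p = 0.41), with Btg1 at 0.97 and Gadd45b at -0.96. Cholesterol and fatty acid synthesis genes had a median of -0.11 (adjusted p = 0.17), with Abca1 at 0.77 and Dhcr7 at -0.49. Camera called this last list downward without vehicle 2 (5.7e-05) and without combination 1 (0.025), which unbalances the numbers, and these genes were lower on the arrays numbered 2 by -0.49 with vehicle and -0.28 with the combination.

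Markers of the cell types that the LK gate may hold or let through were examined next. All 11 measured erythroid markers were lower, with a median of -0.42, and the transferrin receptor gene Tfrc fell 1.73-fold from 10.77 ± 0.03 to 9.98 ± 0.07 over the list alone in limma. Rhd differed by -0.57. Camera called the list downward (adjusted p = 0.0079, and adjusted p = 0.75 with an estimated correlation), but not without vehicle 1 (0.68, with the median at 0.13) or combination 2 (0.082, at -0.12), against medians of -0.90 without vehicle 2 and -0.79 without combination 1. The markers were lower on the arrays numbered 2, by -0.79 with vehicle and -0.58 with the combination. The call of Tfrc was lost without any 1 array, while its log2 difference stayed between -0.84 and -0.74. Granulocyte and monocyte progenitor markers had a median of -0.24 (camera adjusted p = 0.022, and adjusted p = 0.75 with an estimated correlation), with Csf1r at 9.45 ± 0.46 and 8.53 ± 0.20 and Fcgr3 at 10.42 ± 0.34 and 11.93 ± 0.47. Camera did not call it without vehicle 2 (0.43, with the median at -0.11) or combination 1 (0.89, at -0.11), and the median was -0.37 without combination 2. The markers were higher on the arrays numbered 2, by 0.48 with vehicle and 0.31 with the combination, and 3 members passed alone without vehicle 1 and 1 without combination 1.

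Among 15 macrophage and dendritic cell markers, 1 rose and 3 fell over the list alone. The lectin receptor genes Cd209a and Mrc1 fell 4.74-fold and 4.57-fold, Adgre1 fell 1.47-fold, and the complement gene C1qb rose 2.12-fold. These 4 calls became 1 without vehicle 2 and 2 without combination 1, while the log2 difference stayed between -2.69 and -1.69 for Mrc1, -0.65 and -0.46 for Adgre1 and 0.99 and 1.18 for C1qb. The median was 0.13 and the mean -0.20, with camera pointing down (adjusted p = 0.97). Of 13 mature neutrophil markers only Cxcr2 rose over the list alone (3 passed without vehicle 1), with Mcemp1 at 7.27 ± 0.29 and 8.16 ± 0.17 and a median of 0.14 (camera adjusted p = 0.086). These markers were lower on the arrays numbered 2, by -1.30 with vehicle and -0.79 with the combination, so leaving out an array, which unbalances the numbers, gave medians of 1.10 without vehicle 1 and 1.02 without combination 2, where camera called the list upward (1.2e-05 and 0.0011), and of -0.40 without vehicle 2 and -0.25 without combination 1. In the megakaryocyte list Ppbp alone rose, 45.8-fold, with Clec1b at -0.47 and a median of 0.06 (adjusted p = 0.95). Gzmb and Hdc rose 2.89-fold and 3.26-fold among 12 mast cell and basophil markers, with a median of -0.15, a mean of 0.11 and camera pointing down (adjusted p = 0.41). That count of 2 was 1 without vehicle 1, 1 without combination 1 and 0 without combination 2, with log2 differences between 1.34 and 1.72 for Gzmb and 1.29 and 2.12 for Hdc. The leptin receptor gene Lepr rose to 7.57 ± 0.65 from 4.08, which lies within the background range, 11.2-fold or more, among stromal and endothelial markers (median 0.01, adjusted p = 0.41), where Pdgfrb differed by 0.21. No B cell marker passed (median -0.15, adjusted p = 0.061; Blnk at -0.90, Ebf1 at -0.55). No T and NK cell marker passed (median 0.08, adjusted p = 0.16; Il7r at 1.99, Cd8a at 0.36), while 1 did without combination 1. Without vehicle 1, camera called the B cell list downward (5.2e-06), and its markers were higher on the array numbered 2 by 0.52 with vehicle and by 0.04 with the combination.

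Interferon response genes separated the arrays by replicate number. All 27 measured genes were lower on the array numbered 2 than on the array numbered 1 in both groups, by a median of 12.1-fold with vehicle and 10.5-fold with the combination. Rsad2 was at 12.18 on vehicle 1 and 4.55 on vehicle 2, and at 12.16 and 5.98 on the combination arrays. Between the groups this list had a median of -0.07 (-0.17 for number 1 and -0.11 for number 2), with 0 members past limma's test over the list alone and a camera adjusted p of 0.44. Gbp2 differed by -0.87 and Ifit2 by -0.92. Leaving out an array unbalanced the numbers and gave medians of 1.39 without vehicle 1, -2.14 without vehicle 2, -1.96 without combination 1 and 1.698 without combination 2. The granule genes Ngp, Camp and Ltf were also lower on the arrays numbered 2, Ngp at 14.82 and 8.69 with vehicle. The hybridisation control spikes bioB, bioC, bioD and cre were brighter on the arrays numbered 2 by 0.27 to 0.62 in both groups. The split by number was thus shared by both groups.

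**Figure D3:**
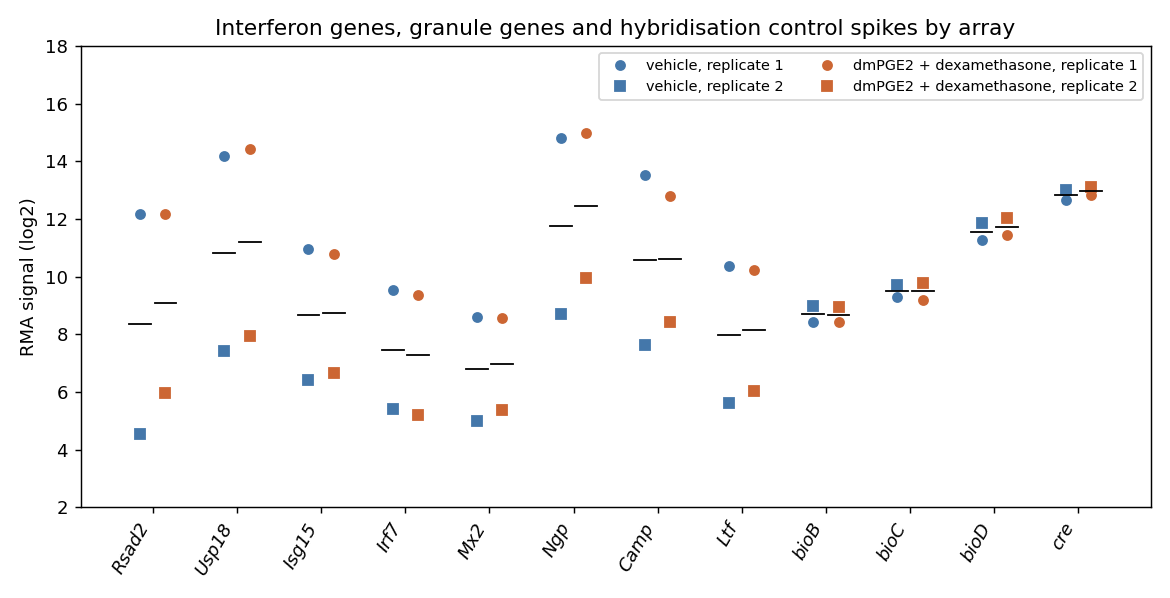
RMA signal (log2, vertical axis) of 5 interferon response genes, 3 granule genes and 4 hybridisation control spikes on the 4 arrays, with vehicle in blue, the combination in orange, circles for replicate 1, squares for replicate 2 and a black line at each group mean. For interferon and granule genes the circles lie above the squares in both groups, as for Rsad2 (12.18 against 4.55 with vehicle), and for the spikes the squares lie above the circles.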

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

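The fit, the gene lists and the alternatives were chosen before the data were examined, except for the control rows, the repeated features and the protein-coding background, which were added after. The genes named beyond the naming rule and the tests of explanations given further below were also chosen after. The labels do not say that the replicate numbers pair samples, and 2 pairs do not show what the numbers stand for. Interferon genes, granule genes and control spikes nevertheless split by number the same way in both groups. The numbers thus mark a difference that both groups share. Deviations from the group means of arrays with the same number correlated at 0.328 across features. The main fit leaves such a shared difference in its residual. The fit with the replicate block gave 19 features, with 10 genes higher (Tlr8, Il18rap, F13a1, Il1r2, Ccr1, Havcr2, Trem1, Cd33, Cytip and Vcan) and 1 lower (Lpl), and 15 lists by camera. These were the 12 and, beyond them, interferon response genes, downward (adjusted p = 0.039), and mature neutrophil markers and glycolysis and hypoxia genes, upward (0.0011 and 0.027). With the block fry called glycolysis and hypoxia genes (0.046) and not glucocorticoid receptor targets (0.15). Its test in either direction then passed for 0 lists (adjusted p = 0.060 for homing and adhesion molecules). The block leaves fewer residual degrees of freedom than the 2 of the main fit, which costs fry power. The calls that fry lost therefore do not show that the block undid them. In limma Ptger4 passed over its list (0.060 without the block, 0.041 with it). The count of 2 features and 1 gene higher became 0 and 0 with an intensity trend, with either filter on dim features, after a second quantile normalization, with the control rows kept and without any 1 array (0 to 0). It was 1 feature among those with 1 symbol. Fewer arrays or a changed variance prior are part of these settings, and the cause was not tested further. At an adjusted p of 0.10 there were 11 features, with 5 genes higher and 1 lower, and at the console's threshold 716, with 217 higher and 103 lower. The adjusted p of Tlr8 ranged from 0.029 to 0.69. Of the 12 lists called by camera, 0 were called with an estimated correlation, a setting that also leaves only 2 degrees of freedom. For glucocorticoid receptor targets the estimated correlation was -0.0030, below the preset 0.01, so correlation did not end that call. Without 1 array 8 to 12 lists were called, and 6 to 10 of the 12 were among them. Antigen presentation genes also lost their call with either filter, after quantile normalization, after centring and among protein-coding genes (adjusted p = 0.056 to 0.16). With the filter at the median, stem cell, oxidative phosphorylation and granulocyte and monocyte progenitor lists lost theirs (0.071 to 0.096), the last also after quantile normalization (0.11). Mature neutrophil markers gained a call upward with that filter, after quantile normalization and after centring (0.048, 0.043 and 0.030), B cell markers one downward with an intensity trend and after quantile normalization (0.037 and 0.040), and glycolysis genes one upward after quantile normalization (0.036). Each array left out unbalances the numbers and leaves 1 array in a group, assumed to vary like the others. Of 53 calls of members over their list alone, 23 were lost without at least 1 array, and 3 of the 53 log2 differences, those of Fos, Pde4b and Errfi1, moved by over 1.5 times.

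Medians that changed sign without 1 array ranged from -2.14 to 1.698 for interferon genes, -0.32 to 0.012 for antigen presentation, -0.30 to 0.0086 for G2/M genes, -0.90 to 0.13 for erythroid markers, -0.40 to 1.10 for mature neutrophil markers, -0.33 to 0.17 for cholesterol and fatty acid synthesis, -0.39 to 0.071 for B cell markers, -0.28 to 0.15 for megakaryocyte markers, -0.19 to 0.040 for homing molecules, -0.068 to 0.042 for heat shock genes, -0.00047 to 0.14 for macrophage markers and -0.012 to 0.045 for stromal markers. For DNA replication genes the median kept its sign (-0.42 to -0.0020) and camera's direction turned. The NF-kB median was -0.019 after quantile normalization and -0.039 after centring. Single genes ranged from -0.10 to 0.27 for Ido1, -0.51 to 0.18 for Nr3c1 and -0.12 to 0.021 for Nr4a2. Of 1183 values for named genes over all settings, 1165 kept direction and side of the threshold, 9 lost the threshold, 5 gained it and 4 turned. Of 459 list shifts 384 kept both. Signals near the background, where single probe sets reached 5.55, limit what can be said of dim genes.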

Other observations

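Genes outside the lists, and the list member Irf8, held further large differences, picked after their values were seen. The myeloid lectin gene Cd33 was at 7.63 ± 0.10 with vehicle and 11.23 ± 0.44 with the combination, Clec4e at 7.26 and 10.78, Cd14 at 6.92 and 9.35, and Plaur, the urokinase receptor, at 10.60 and 14.18. Coagulation factor F13a1 was at 8.55 and 11.47, the matrix proteoglycan Vcan at 7.04 and 10.32, the activin antagonist Fst at 4.68 and 7.65, the vitamin D receptor gene Vdr at 6.18 and 9.13, and the differentiation inhibitor Id2 at 6.45 and 9.44. Il18rap, a subunit of the interleukin-18 receptor, was at 6.98 and 10.07 (limma adjusted p = 0.092), and Il1r1, the signalling receptor for interleukin-1, differed by 2.73 beside the 5.99 of the decoy Il1r2. Irf8, a factor of monocyte and dendritic cell development, is a member of the granulocyte and monocyte progenitor list. It was lower, at 7.98 and 6.49, as were, outside the lists, Kmo (7.77 and 6.12), Clec4a3 (7.43 and 5.80) and Cd180 (6.33 and 4.77). None of these passed limma's threshold over all features in the main fit. With the replicate number as a block, Cd33, F13a1, Vcan and Il18rap passed (limma adjusted p = 0.047, 0.047, 0.046 and 0.047). The feature without a listed gene that passed in the main fit has the identifier next to that of Cd33, TC0700002950.mm.1, and the neighbourhood of the pair was not examined.

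Control rows outside the tests were also fitted. Of 5222 negative control rows 838 had an unadjusted p under 0.05 when fitted with the features, 16.05%, and of 1324 positive control rows 152 did, 11.5%, against 3679 of the 65956 features, 5.58%. The negative control rows had array medians of 5.79 to 5.89, above the 3.07 to 3.16 of the background probe sets, and what they measure was not tested. After Benjamini-Hochberg adjustment among the 6732 control rows, 0 passed in limma, with 992 at an unadjusted p under 0.05.

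The tests below were all chosen after the results they measure were seen. The 12 largest upward differences include Cxcr2, Trem1 and Clec4d, genes of mature neutrophils, so a larger share of neutrophils in the combination arrays may account for them. Such cells would bring their other transcripts too. The 12 neutrophil markers outside this set differed by a median of 0.03 (SD 0.66) in number 1 and 0.37 (SD 0.89) in number 2. Mmp8 differed most of all (2.43 over all arrays). The 9 of them other than the granule genes Ngp, Camp and Ltf differed by 0.09 (SD 0.67) and 0.25 (SD 1.01). The 12 genes differed by 4.46 (SD 0.65) and 5.28 (SD 0.55). Picking the 12 genes as the largest fixed that they exceed the markers, but not that the marker medians are small. These medians argue against a larger share as the whole cause. A smaller part stays open, since 11 of the 13 measured markers were higher. Camera also called their list upward with the replicate block (adjusted p = 0.0011). A response of neutrophils carried along in both groups stays open, though the selection of lineage-negative, c-Kit-positive cells should remove mature ones: the 12 genes differed by 1.11 more in number 2 than in number 1 (SD 0.64), but the differences of the markers between vehicle 2 and vehicle 1 (median -1.41, SD 2.20) are too uneven to say how the share of neutrophils differed. A response of the progenitors to the drugs also stays open, as a hypothesis these arrays cannot separate from it.

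The arrays numbered 1 and 2 stood apart in interferon and granule genes, and camera called 12 of the 27 lists between them, 6 of which it also called between the groups. Beside interferon genes these were cholesterol and fatty acid synthesis (adjusted p = 4.7e-09), DNA replication (1.8e-06), G2/M (2.8e-04), MYC and ribosome biogenesis (0.0046) and antigen presentation genes (0.024) and neutrophil (2.3e-11) and erythroid markers (8.8e-04), lower on number 2, and granulocyte and monocyte progenitor (1.4e-04), megakaryocyte (0.0013) and B cell markers (0.0042) and homing molecules (0.017), higher. A difference in hybridisation intensity, which the control spikes show, is argued against as the whole cause: interferon genes shifted by a median of -3.39 in the group where they shifted less, while the spikes shifted by 0.27 to 0.62 the other way. Neutrophil markers were lower by a median of -1.30 on vehicle 2, so a different share of neutrophils between the numbers could go with the interferon shift, although the selection should remove mature neutrophils. The 2 cannot be told apart, since there is 1 contrast of the numbers per group, and no biological explanation was tested, because the labels say nothing of how the numbers differ.

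Of the lists with a mean signal of at least 8, camera called 7 downward, most with small medians, and genes with a signal of 8 to 12 had medians of -0.07 against 0.04 for the dimmest, so a shift that depends on the signal level may underlie them. The median of oxidative phosphorylation genes lay at percentile 14.6 of random lists of matched signal, that of G2/M genes at 5.06 and that of DNA replication genes at 2.86, all above percentile 2.5 though the last only just, in line with such a shift. The medians of MYC and ribosome biogenesis genes (percentile 0, below all 10000 lists), erythroid markers (0.01), granulocyte and monocyte progenitor markers (0.12) and antigen presentation genes (0.98) lay lower. For genes that vary independently, the signal level alone would thus rarely give such medians. Members of these lists can move together, which the random lists ignore (estimated correlations of 0.26, 0.34, 0.74 and 0.073). The percentiles therefore cannot exclude the signal level as their whole cause. A response to the combination stays open for these 4 lists, as does, for the 2 marker lists, a different share of cells. With an estimated correlation, and the 2 degrees of freedom this leaves, camera called none of the 7.

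The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 2 features past the threshold in limma and the highest other gave 21, so 2 of the 3 splits gave as many. That other split follows the replicate number, a structure of the samples, and with the number as a block the real comparison gave 19.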
